A study of Mus musculus with 4 samples.

How the data were processed

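MeRIP-seq was performed on epidermal keratinocytes of control mice at postnatal day 0. Per the labels' protocols, RNA enriched for polyadenylated transcripts was fragmented, incubated with a polyclonal antibody against m6A and recovered on protein-A beads. The 4 libraries are input and IP with replicate numbers 1 and 2, and nothing in the labels says whether the replicates came from separate animals.

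The deposited lists of methylated mRNA sites were made by the authors, and per the file headers they give for each site a position, a length, a transcript, a gene and annotation terms. Site names carry the name of the peak caller MACS, per the deposited lists, and its version is not given in the sources used here. The build is GRCm38, per the submitters' processing notes. The aligner, the filters and the gene annotation are not given in the sources used here. The fold enrichment is the authors' ratio of IP over input at a site and was never below 2. The score is the authors' -10 log10 of the site's p-value, per the file headers, with ties at 3100. The FDR is deposited as a percent and was never below 51.2. Site length and start and end positions are in bases, per the file headers, and 1 was added to each deposited start. A list was deposited for each of 2 samples, but which IP and input libraries entered a list, and whether any were pooled, is not given in the sources used here. The highest peak number was 41306 in list 1 and 52650 in list 2, above the 6038 and 8246 sites held, so the lists hold part of the numbered peaks. No read counts or values per library were used, so the depth per sample is unknown, and the precision of a single site's fold cannot be given. Intervals are 95% Wilson intervals over sites and cover counting error only.

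Symbols were matched to a RefSeq gene table on GRCm38. Gene identifiers of 97.6% of the sites of list 1 and 97.8% of those of list 2 were found in it, and of these sites 98.9% in each list overlapped the annotated gene. The 17 gene lists, with 368 different matched genes, the tests and the rule for named genes were fixed before the data were examined. Of the gene list members, 1 (Krt85) had no match. The title genes are also members of the hemidesmosome list, and no other gene is in more than 1 list.

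Sites were called overlapping when they shared at least 1 base on the same chromosome, without regard to strand, which the lists do not state. The number was compared with 1000 placements of the sites of list 2 at random within the span of all sites of their gene, because exon annotation was not used here. Such placements include introns and understate the overlap by chance where sites lie in exons. Pairs with the largest overlap were taken once each for the correlation of log2 fold enrichment, with 100000 permutations. Gene lists were tested for a site in both lists by a two-sided Fisher's exact test among genes with a site in either list, and for fold enrichment, in lists of at least 5 genes, by 10000 random lists drawn from genes with a site in both. Adjustment was by Benjamini-Hochberg with a threshold of 0.05. The site values served to rank, filter and describe sites and, as log2 fold, entered the correlation across sites and the permutation tests of gene lists and annotation terms. The 2 lists were not treated as replicates of a p per site. The overlap and correlation steps were run on simulated lists, where 2000 of 2000 planted shared sites among 5600 were recovered. A planted correlation of 0.6 came out as 0.617. Planted sites were copies of list 1 sites shifted by a part of their length, so their overlap was fixed in advance. The simulation checks the computation and not how well shared sites are found in real lists.

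Named genes are the 3 title genes, the 10 genes with the highest lower fold of both lists at an overlapping site, the 8 genes with the most overlapping sites, up to 4 members per gene list with the highest mean fold at an overlapping site, up to 5 members without a site from the m6A and hemidesmosome lists, and the 5 genes per list with the highest fold and no site in the other list. The immediate early genes and the members of the hemidesmosome list found in a single list are named in addition.

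Alternatives were the 50% of each list with the higher fold or significance, a reciprocal overlap of 50%, equal numbers of the strongest sites, each list alone, merging of touching sites, the score in place of fold, and all protein-coding genes as background. Added after the data were seen were sites with a p of 1e-05 or less, placement within the annotated gene, genes with 2 or more separate sites, sharing by overlapping site, matching on gene span or on the number of sites, the hemidesmosome list without the title genes, and tests of the deposited annotation terms. The position of sites within transcripts and sequence motifs were not analysed here. An annotation term and the values of a marker gene are not reported here. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.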

Results

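N6-methyladenosine (m6A), a methyl mark on adenosines of messenger RNA, was mapped in epidermal keratinocytes of newborn control mice (postnatal day 0, genotype K14Cre, Mettl14 F/+) by methylated RNA immunoprecipitation sequencing (MeRIP-seq). In this assay RNA fragments are pulled down with an antibody against m6A (IP) and sequenced beside the unselected fragments (input), and places where the IP exceeds the input are called as sites. The 4 libraries form 2 groups, control input and control m6A IP, with 2 libraries in each. The data are 2 lists of sites, referred to as list 1 and list 2, each with a position, a fold enrichment, a score and a false discovery rate (FDR) per site, all of them the authors' own values. The lists carry no read counts, so that the depth of each library is unknown, and the labels do not tie a list to a replicate number. There is no second genotype in these lists, so all comparisons are between the lists, between genes or between gene groups. Positions are on GRCm38, counted from 1.

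The first question was which transcripts carried sites. Ranked by the lower value of the 2 lists, the most enriched site was in Rdx, which encodes radixin, a linker of actin to the plasma membrane, at chromosome 9, 52073154 to 52073284, with a fold enrichment of 8373.25 in list 1 and 5946.2 in list 2. The predicted gene Gm10800 (9069.52 and 2057.97) was next, followed by Ubr4, which encodes a ubiquitin ligase, with 1864.64 and 3016.25 at chromosome 4, 139457532 to 139457771. The other genes among the 10 highest by this rank were Ccdc186 (2349.2 and 1774.69), Col22a1 (1758.12 and 1832.28), Pcdhb22 (2578.99 and 1696.06), Trio (2867.5 and 1527.79), Brms1l (1579.66 and 1397.42), Wdpcp (1807.51 and 1280.72) and the kinase gene Hipk2 (1636 and 1247.9). The values of Gm10800 and of Pcdhb22, a member of a gene cluster with close relatives, are uncertain because reads from similar sequences could not be told apart here. Sites with a high fold in a gene without any site in the other list included D7Ertd443e (2346.28), Herc3 (2048.21), Fgd5 (1920.56), Pdlim3 (1791.59) and Atp8b1 (1774.06) in list 1, and Abhd2 (1398.25), the histone gene H3c7 (1147.18), Nf1 (953.53), Hspa4l (860.05) and Etnk1 (858.71) in list 2.

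List 1 held 6038 sites in 4187 genes and list 2 held 8246 sites in 5045 genes. A single site was present in 72.6% of the genes of list 1 and 65.6% of those of list 2, and the most sites in a gene were 13 in Dst, which encodes a cytoskeletal linker of hemidesmosomes, and 20 in the nuclear envelope gene Syne2. The median fold enrichment was 11.6 in list 1 (quartiles 4.41 and 44.1) and 11.9 in list 2 (4.29 and 41.4), and the median site length was 183 and 169 bases. Sites with a p of 1e-05 or less made up 73.7% of list 1 and 76.9% of list 2, while the highest p in the lists was 0.442 and 0.466. The lowest FDR of any site was 55.7% in list 1 and 51.2% in list 2, and 59.2% and 51.5% of the sites stood at 100%. Without counts per library no site could be tested against the spread between replicates.

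The second question was how far the lists held the same sites. Macf1, which encodes a linker of actin and microtubules, had the most overlapping sites with 8, followed by the histone methyltransferase gene Nsd1 and the desmosomal plaque gene Dsp with 7 each. Eif3a, Syne2 and the cadherin gene Fat1 had 6 each, and Prrc2c and Sh3pxd2a had 5 each. Of the 6038 sites of list 1, 2216 overlapped a site of list 2 by at least 1 base (36.7%, 95% Wilson interval 35.5 to 37.9), and 2209 of the 8246 sites of list 2 did so in return (26.8%, 25.8 to 27.8). When the sites of list 2 were placed at random within the span of all sites of their gene, a median of 1004 overlapped (central 95% of placements 981 to 1031; one-sided permutation p = 0.001, the smallest that 1000 placements can give). Restricted to genes with 2 or more separate sites, where a placement can move a site, a median of 253 of 5630 sites overlapped by chance and 1457 did so in the data. With placement anywhere in the annotated gene the median was 131 of 7871 sites against 2073 in the data, so the size of the excess, 2.20 times in the span of sites and 15.8 times in the annotated gene, depended on where sites were placed. The placements included introns, which understates the overlap by chance where sites lie in exons, and no placement within exons was run.

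**Figure D1:**
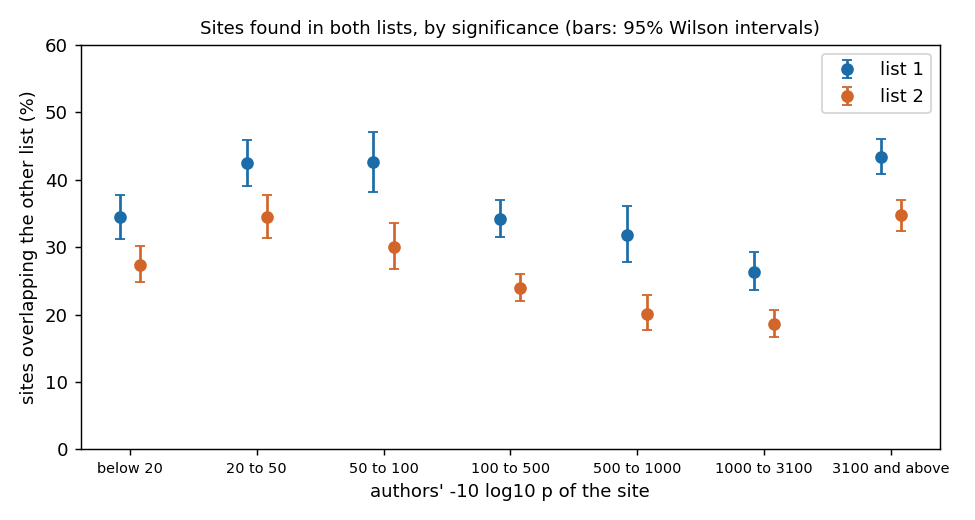
Percentage of sites overlapping a site of the other list (vertical axis) by the authors' -10 log10 p of the site (horizontal axis), with list 1 in blue and list 2 in orange and bars for 95% Wilson intervals. In list 1 the share was 42.4% from 20 to 50, 26.4% from 1000 to 3100 and 43.4% from 3100 upward.

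The share of overlapping sites did not rise steadily with the significance of the site. In list 1 it was 34.4% below a -10 log10 p of 20, 42.6% from 50 to 100, 26.4% (23.7 to 29.2) from 1000 to 3100 and 43.4% (40.9 to 46.0) from 3100 upward, the value at which 1393 sites were tied. In list 2 the same classes gave 27.4%, 30.0%, 18.6% (16.6 to 20.7) and 34.7% (32.4 to 37.0). Sites longer than 600 bases overlapped more often, with 60.2% in list 1 and 51.1% in list 2, and sites of up to 50 bases less often, with 30.2% and 19.6%, although a long site also overlaps more by chance.

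At the level of genes, 2607 had a site in both lists, 1580 in list 1 alone and 2438 in list 2 alone. Genes in both lists made up 62.3% of the genes of list 1, 51.7% of those of list 2 and 39.4% of the 6625 genes in either. Independent lists of these lengths drawn from 21900 protein-coding genes would share 965, a value that leaves out that only expressed genes can have a site. An overlapping site was present in 1803 of the 2607 genes (69.2%), and 804 genes had sites in both lists that did not overlap. With sites at a p of 1e-05 or less, 34.6% of genes were in both lists.

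The third question was whether overlapping sites were enriched to the same degree. Col22a1 (1758.12 and 1832.28), the ribosomal protein gene Rpl17 (651.39 and 671.17) and Flg2, which encodes a filaggrin-family protein of the cornified layer (1231.25 and 1299.59), had close values in both lists. Grhl3, a regulator of the epidermal barrier, had 496.26 in list 1 and 16.89 in list 2 at the same interval, and Plec, which encodes the hemidesmosomal linker plectin, had 9.69 and 136.82. Over 2202 pairs of overlapping sites, log2 fold enrichment correlated across sites with a Pearson r of 0.564 and a Spearman rho of 0.537 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give, 2 relations computed on fold). The median log2 difference of list 2 minus list 1 was -0.11 (quartiles -1.10 and 0.78). The values lay within 2-fold of each other in 51.8% of pairs and differed by more than 4-fold in 24.9%. Sites are not independent replicates, and a correlation across sites says nothing of the spread at a single site.

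**Figure D2:**
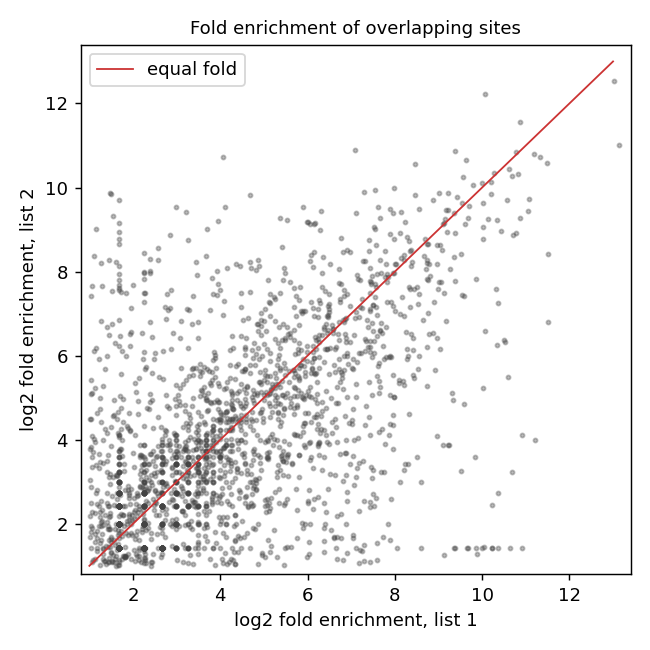
Log2 fold enrichment in list 1 (horizontal axis) and list 2 (vertical axis) of the 2202 pairs of overlapping sites, with 1 point per pair and a red line at equal values. The points follow the line with a Spearman rho of 0.537 and a wide spread, and 24.9% differ by more than 4-fold.

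The series names 3 transcripts of hemidesmosomes, the structures that anchor basal keratinocytes to the basement membrane, and asks about their m6A sites: Col17a1 (collagen XVII), Itga6 and Itgb4 (the subunits of integrin α6β4). All 3 genes had at least 1 site in each list, but only Itga6 had a site that overlapped between the lists. That site lay at chromosome 2, 71855854 to 71856472 in list 1 (fold 24.02, -10 log10 p 3100, FDR 55.8%) and 71855854 to 71857441 in list 2 (fold 6.31, 752, FDR 88.3%), 1955 and 986 bases from the upper end of the gene, which spans 71786886 to 71858427. Itga6 had 1 further site in list 1 (71853534 to 71853866, fold 14.12) and 4 further sites in list 2, the strongest at 71825509 to 71825719 with a fold of 18.82. The overlap did not reach 50% of both sites.

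Col17a1 had 1 site in list 1, at chromosome 19, 47673334 to 47673405, with a fold of 14.35 and an FDR of 64.6%. List 2 held 4 sites in Col17a1, of which those at 47685535 to 47685597 (fold 33.42) and 47691813 to 47691861 (fold 22.52) had an FDR of 59.5%, while those at 47650726 to 47650866 (fold 2.49) and 47655262 to 47655268 (fold 3.06) had an FDR of 100%. The nearest Col17a1 sites of the lists were 12130 bases apart. Itgb4 had 1 site in each list, at chromosome 11, 115984037 to 115984201 in list 1 (fold 2.53, -10 log10 p 15.6, FDR 100%) and 115979076 to 115979158 in list 2 (fold 58.86, 3100, FDR 59.5%), 4879 bases apart. By the highest fold per gene, Col17a1 ranked 2045 of 4187 genes in list 1 and 1674 of 5045 in list 2, Itga6 ranked 1642 and 2199, and Itgb4 ranked 4033 and 1237. Exon, UTR and strand annotation was not used here, so the part of the transcript in which a site lies is not given.

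**Figure D3:**
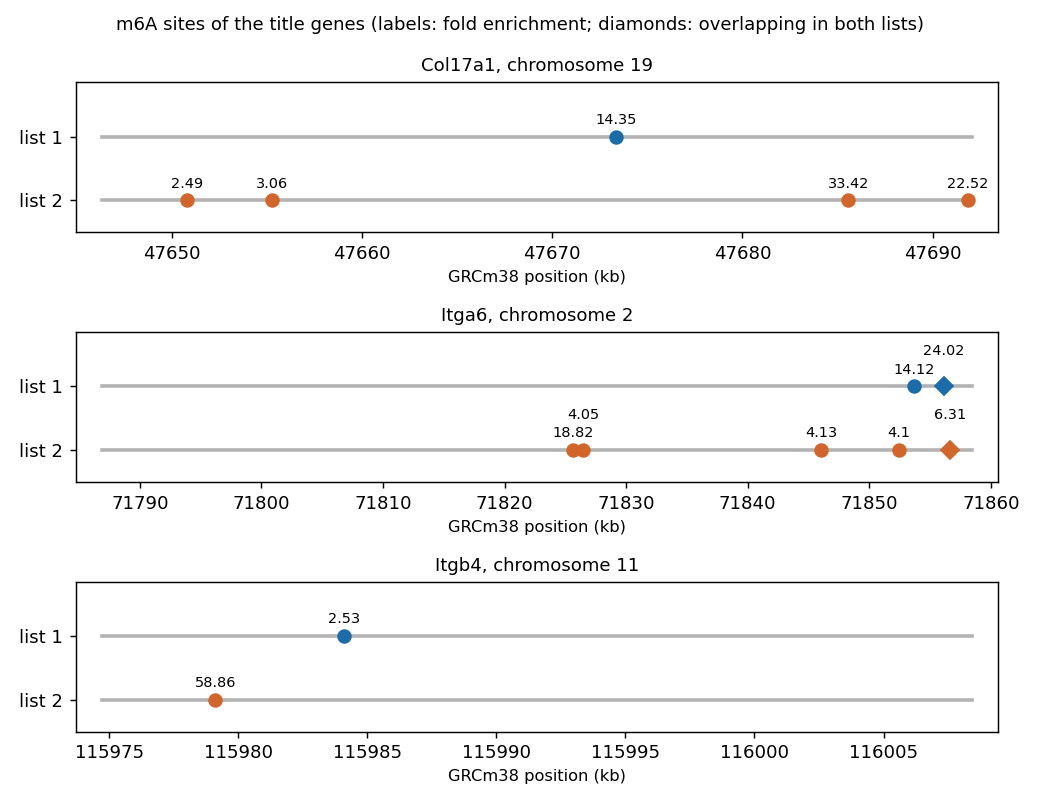
Sites of Col17a1, Itga6 and Itgb4 along the gene (horizontal axis, GRCm38 position in kb; grey line, the annotated gene) in list 1 (blue) and list 2 (orange), labelled with their fold enrichment. Diamonds mark the overlapping site of Itga6, with folds of 24.02 and 6.31, and no other site overlaps.

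Genes of hemidesmosomes and basement membrane adhesion had sites in both lists more often than other genes with a site. Of 24 members, 22 had a site, 18 of them in both lists (81.8% against 39.2% of other genes; odds ratio 6.98, two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 0.00124 over 17 gene lists). Examples with an overlapping site were Dst (folds 7.16 and 464.76), the laminin genes Lamc1 (323.71 and 142.21) and Lama3 (32.93 and 96.41), and Plec. At these sites the FDR in list 1 was 100% for Dst and Plec and below 100% for the laminin genes. In list 2 it was 59.5% for each. Lamb1 and Col4a2 had sites in list 2 alone, Col7a1 and Nid1 in list 1 alone, and Cd151 and Src in neither. The list includes the 3 genes named by the series, which are not independent evidence, and without them 15 of 19 genes were in both lists (78.9%, exact test, adjusted p = 0.00996). Against random genes of similar genomic span the permutation test gave an adjusted p of 0.0238. Genes were not matched on expression, for which the lists give no value, so higher expression of these genes was not separated from methylation. Genomic span includes introns, and this test was not matched on transcript length or on the number of sites. Dst had 13 and 18 sites in list 1 and list 2, and Plec had 5 and 12. At the level of overlapping sites 8 of the 22 genes were shared, 36.4% against 27.2% of other genes (exact test, adjusted p = 0.763), so the difference held for genes and was not detected for positions. Over all alternatives the adjusted p ranged from 1.28e-11 to 0.960, and it was 0.0987 and 0.0960 in the 50% of each list with the higher fold or significance.

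Immediate early genes, the transcription factors and regulators that respond first to stimulation, showed the opposite count. Of 20 members, 12 had a site and none of these had it in both lists (0% against 39.4% of other genes, Fisher's exact test, adjusted p = 0.0414). Fos (23.66), Jun (7.6), Egr1 (29.47), Egr2 (41.43) and Klf2 (26.21) had a site in list 1, and Fosl2 (3.47), Jund (2.64), Egr3 (30.37), Atf3 (2.45), Dusp1 (99.07), Dusp6 (12.13) and Nr4a1 (12.65) in list 2. These 12 genes are named in full because of their count and were chosen after their values were seen. Against random genes of similar span the permutation test gave an adjusted p of 0.222, and the call was lost under each of the alternatives, with adjusted p from 0.192 to 0.492. No immediate early gene could be in both lists under any of them, because none was so in the full lists. The difference from the comparison genes ranged from -30.8 to -11.5 percentage points.

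**Figure D4:**
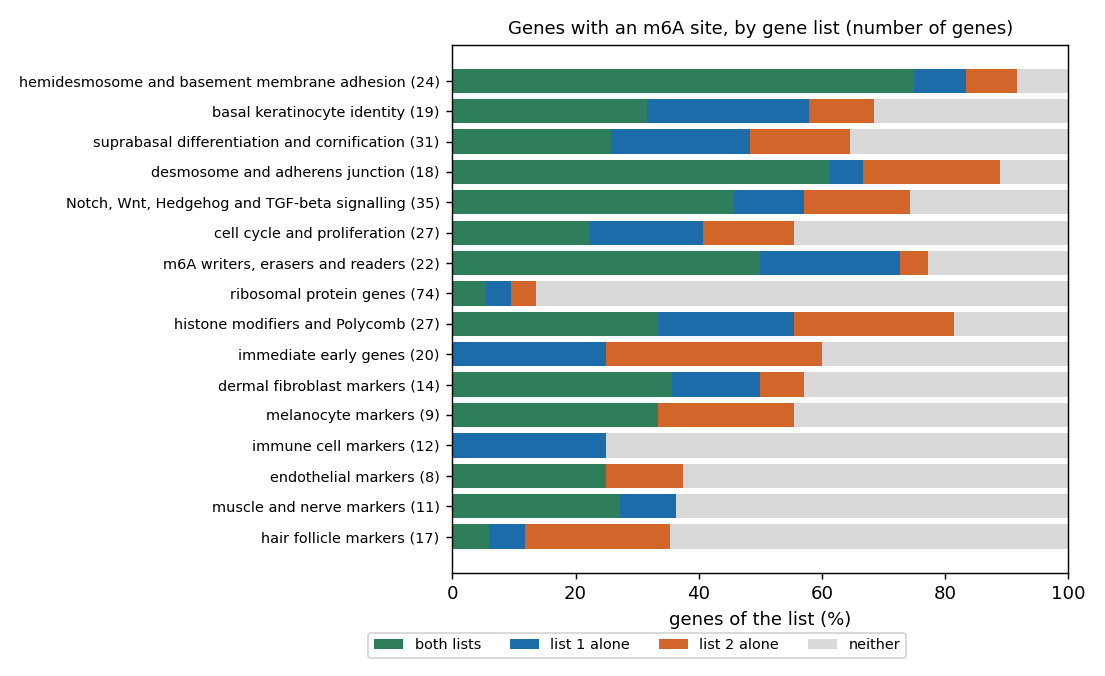
Percentage of the genes of each gene list (horizontal axis, number of genes in brackets) with a site in both lists (green), in list 1 alone (blue), in list 2 alone (orange) or in neither (grey). Hemidesmosome and basement membrane genes had 18 of 24 in both lists, and immediate early genes 0 of 20.

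The cell-cell junction genes of desmosomes and adherens junctions had 16 of 18 members with a site, 11 of them in both lists (68.8%, exact test, adjusted p = 0.110). Dsp carried an overlapping site over the same interval in both lists, chromosome 13, 38191361 to 38193655 (85.65 and 108.66), and Ctnna1 (38.33 and 113.32), Dsc3 (41.03 and 9.75) and Cdh3 (9.08 and 15.37) also had one. Genes of Notch, Wnt, Hedgehog and TGF-beta signalling had 26 of 35 members with a site and 16 in both lists (61.5%, exact test, adjusted p = 0.110), with overlapping sites in Fzd6 (177.2 and 33.39), Lrp6 (15.88 and 187.74), Rbpj (101.93 and 15.48) and Dll1 (71 and 23.1). The m6A writers, erasers and readers had 17 of 22 members with a site and 11 in both lists (64.7%, exact test, adjusted p = 0.151). Eif3a (1032.65 and 531.01), Ythdc1, which encodes a nuclear reader (399 and 115.28), Zc3h13 (296.68 and 39.5) and Rbm15 (110.32 and 46.97), both of the writer complex, had overlapping sites. Mettl3 and Mettl14, the catalytic and RNA-binding subunits of the methyltransferase, had no site in either list, nor had Cbll1, Ythdf1 and Igf2bp3. None of these 3 gene lists passed the adjusted threshold of 0.05. Among the overlapping sites named for them, the FDR was 100% only for Lrp6, in list 1.

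Keratinocyte genes did not differ detectably from other genes in the share present in both lists. Of 19 basal identity genes 13 had a site and 6 had it in both lists (46.2%, exact test, adjusted p = 1), including Trp63, which encodes the basal transcription factor p63 (48.16 and 31.81), Grhl3, Fgfr2 (11.67 and 49.88) and Bnc1 (21.31 and 3.26). The list was fixed beforehand and holds Grhl3, named above as a regulator of the epidermal barrier, so its name does not describe every member. Of 31 suprabasal differentiation and cornification genes 20 had a site and 8 had it in both lists (40.0%, exact test, adjusted p = 1), including Flg2, the transcriptional repressor gene Prdm1 (330.1 and 364.1), the lipid transporter gene Abca12 (31.19 and 64.1) and Evpl (47.08 and 12.69). Cell cycle genes had 15 of 27 members with a site and 6 in both lists (exact test, adjusted p = 1), with overlapping sites in Mki67 (3.86 and 94.8), Mdm2 (18.63 and 55.18), Mycn (30.15 and 10.96) and Ccnd2 (21.7 and 6.14). Histone modifier and Polycomb genes had 22 of 27 and 9 in both (exact test, adjusted p = 1). Ribosomal protein genes had a site in 10 of 74 members, 4 of them in both lists (exact test, adjusted p = 1), with overlapping sites in Rpl17, Rps12 (44.84 and 85.45) and Rpl7a (20.27 and 23.54), and as genes with many processed copies they are uncertain. Among the overlapping sites named in this paragraph, the FDR was 100% in list 1 for Fgfr2, Abca12, Mki67 and Mdm2. In list 2 it was 100% for Grhl3 and Bnc1, and it was below 100% at the others.

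Markers of other cell types also carried sites. Dermal fibroblast markers had a site in 8 of 14 genes, 5 of them in both lists (exact test, adjusted p = 0.580), with overlapping sites in Postn (9.34 and 43.2), Fn1 (14.11 and 10.63) and Lum (7.97 and 12.02). At these overlapping sites the FDR was 100% in both lists for Fn1 and Lum, and 82.2% and 59.5% for Postn. Fn1 had 8 sites in list 2, with a highest fold of 281.28. Melanocyte markers had a site in 5 of 9 genes, 3 in both lists (exact test, adjusted p = 0.639), including Tyr (2.35 and 26.45) and Dct (7.21 and 13.6). At these overlapping sites the FDR was 100% and 64.4% for Tyr and 66.4% and 79.7% for Dct. Endothelial markers had 3 of 8 and 2 in both (exact test, adjusted p = 0.801), namely Flt1 (385.73 and 2.67) and Kdr (3.19 and 2.67), but the -10 log10 p was 7.2 for Flt1 in list 2 and 14.12 and 17.34 for Kdr, with an FDR of 100% at these 3 sites. Muscle and nerve markers had 4 of 11 and 3 in both (exact test, adjusted p = 0.580). Overlapping sites included those of Mbp at 11.16 and 2.67 and Myh3 at 4.78 and 2.67. Both of these had a -10 log10 p of 7.2 and an FDR of 100% in list 2. Another site of Mbp in list 2 had a fold of 93.04 and a -10 log10 p of 3100. Hair follicle markers had 6 of 17 and 1 in both, Lgr6 (exact test, adjusted p = 0.639). The overlapping site of Lgr6 (2.1 and 12.02) had an FDR of 100% in both lists. At other sites Lgr6 reached a fold of 27.64 in list 1 and 16.24 in list 2. Immune cell markers had 3 of 12, all 3 in list 1 alone and none in both (exact test, adjusted p = 0.580). The sites of these 3 genes had a -10 log10 p of 3100 and folds from 10.57 to 383.7. The 3 genes named by the series, tested as a list of their own, gave an adjusted p of 0.173 by Fisher's exact test.

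Enrichment itself was compared between gene lists by the highest log2 fold per gene, averaged over both lists. Histone modifier and Polycomb genes had the highest median, 7.59 over 9 genes against 4.31 in random lists of equal size, at percentile 99.97 of 10000 random lists (two-sided permutation p = 0.0008, adjusted p = 0.00720 over 9 gene lists). Overlapping sites of this group were in the histone methyltransferase genes Kmt2a (220.93 and 292.47), Setd1b (176.87 and 236.81) and Setd2 (145.17 and 120.36) and in the remodeller gene Chd4 (239.11 and 155.86). Against random genes with about as many sites the difference was 1.65 in place of 3.29 (permutation test, adjusted p = 0.130). It was 1.60 with list 1 alone, 1.39 with list 2 alone, and 1.55 and 1.53 in the 50% of each list with the higher fold or significance, and the call was lost under each of these alternatives, with adjusted p from 0.102 to 0.505. The remaining 8 gene lists did not pass the threshold: the m6A machinery had a median of 5.71 (permutation test, adjusted p = 0.454), cell cycle 5.17, suprabasal differentiation 5.02, signalling 4.84, hemidesmosome and basement membrane 4.77 and basal identity 4.43, with desmosome genes at 4.05 and fibroblast markers at 3.29 below the random median (adjusted p from 0.454 to 0.922).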

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

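Tests with sites at a p of 1e-05 or less, by overlapping site pair, matched on gene span or on the number of sites, without the title genes, and with placement in the annotated gene or among genes with 2 or more sites were chosen only after the result was seen. No paired analysis was possible because the lists already contrast IP with input and give no value per library. The excess of overlapping sites over random placement, which includes introns and understates chance where sites lie in exons, and the correlation of fold between the lists stayed past the threshold under all alternatives run for them (overlap from 19.4% to 26.3% against 1.66% to 11.9% by chance, rho from 0.541 to 0.671). Genes in both lists, 39.4%, fell to 30.7% in the 50% of each list with the higher fold, 28.4% in the more significant 50%, 34.6% at a p of 1e-05 or less and 24.0% by site pairs with a reciprocal overlap of 50%, each of which leaves or counts fewer sites. Distinct sites, 12060 over both lists, were 6038 to 8246 with each list alone. Title genes with an overlapping site, 1, were 0 at the higher fold and at the reciprocal overlap, and with each list alone 3 had any site. Gene lists called for detection, 2, were 0 at the higher fold, 0 at the higher significance, 0 by reciprocal pairs, 0 by overlapping pairs, 1 matched on gene span and 9 with all protein-coding genes as background, which also tests expression. Gene lists called for fold, 1, were 0 in all alternatives: 0 at the higher fold, 0 at the higher significance, 0 matched on the number of sites and 0 with each list alone. Neither test of gene lists was run on the sites at a p of 1e-05 or less. Differences between a gene list and other genes that changed sign, none of them past the threshold in either form, were as follows, and the cause was not tested. In percentage points of genes in both lists, basal identity became -0.692 at the higher fold and -5.39 at the higher significance. Suprabasal differentiation became -9.74 at the higher significance, -4.06 by reciprocal pairs and -2.25 by overlapping pairs. Signalling became -4.83 and -0.323 by these pairs, ribosomal protein genes -6.08 with all coding genes and histone modifiers -1.85 matched on span. In log2 fold, hemidesmosome genes became -0.65 at the higher fold, -0.75 at the higher significance and -0.60 matched on sites, and signalling -0.41 and -0.45 at the higher fold and significance. Cell cycle became -0.69 at the higher significance and -0.0025 matched on sites, and basal identity -0.55 matched on sites. With each list alone suprabasal differentiation ranged from -0.16 to 0.72, desmosome from -0.32 to 0.26 and fibroblast markers from -0.81 to 0.54, the changed sign being that of list 2 alone. Of the other settings for single gene lists 58 kept direction and side of the threshold, 6 gained and 15 lost the call. The alternatives for the location of sites in transcripts and for sequence motifs were not run. Depth is unknown, so what it limits at a single site cannot be given.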

Other observations

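All tests of annotation terms, the tests on sites at the highest significance and on identical site starts, and those matched on gene span or number of sites were chosen only after the result was seen.

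Genes annotated to focal adhesion, the contacts of cells with the matrix, had sites in both lists more often than other annotated genes, with 100 of 166 (60.2% against 39.1%; two-sided Fisher's exact test, adjusted p = 3.92e-05 over 522 terms), and the pathway of the same name gave 68 of 113 (adjusted p = 0.003). Cell junction (169 of 332, 50.9%), cell projection (154 of 298), cytoskeleton (250 of 525), neuronal cell body (110 of 215) and cell cortex (34 of 54) were also higher. Metabolic pathways (115 of 377, 30.5% against 41.7%, exact test, adjusted p = 0.00474) and mitochondrion (157 of 500, 31.4% against 40.4%, adjusted p = 0.00651) were lower. All 9 called terms kept an unadjusted p below 0.05 against random genes of similar span, with the highest p at 0.0364. These terms share genes with each other and with the hemidesmosome list, and genes were not matched on expression or transcript length.

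By the highest fold per gene, 16 of 441 terms were called, 12 higher and 4 lower (rank-sum permutation test, adjusted). Median log2 fold was 5.44 for DNA repair against 4.26 for other genes (permutation test, adjusted p = 0.00331), 5.12 for cytoskeleton against 4.25 (adjusted p = 0.00220) and 6.26 for nuclear chromosome against 4.30 (adjusted p = 0.0184). It was 3.56 for extracellular space against 4.36 (permutation test, adjusted p = 0.0184) and 2.50 for calcium signalling against 4.14 (adjusted p = 0.0302). Against genes with about as many sites, 6 of the 16 kept an unadjusted p below 0.05, namely these 5 and the response to DNA damage. Nucleoplasm (permutation p = 0.251), chromatin modification (p = 0.625) and microtubule (p = 0.498) did not.

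Most sites of a list had no partner in the other, and the share with a partner did not rise steadily toward the most significant sites. Calls at nearby genomic positions account for few of the unpartnered sites. Of 3822 such sites of list 1, 5.21% (4.55 to 5.96) lay within 500 bases of a site of list 2. Neighbouring calls on both sides of an intron can lie farther apart on the genome, so this test does not cover them. Weak sites by the authors' score were not the only ones to lack a partner. Of the sites of list 1 at the highest significance, 43.4% (40.9 to 46.0) had one. The lowest FDR in list 1 was 55.7%, so false calls among these sites were not excluded. Unequal list lengths do not account for it either, since 36.7% of the shorter list recurred in the longer one and 23.2% (21.7 to 24.8) did with the same number of strongest sites from each, although that last test also loses partners among weaker sites. False calls, differences in depth or IP efficiency between libraries, and differences between the replicate samples may contribute and remain open. A biological explanation was not tested.

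Of the 12 immediate early genes with a site, none had it in both lists. Random genes of similar span gave no shared gene in 1.75% of 10000 sets, below a bound set beforehand at 5%. That bound left out that 17 gene lists were tested, and after adjustment over them the two-sided permutation p was 0.222. Matching on the number of sites gave 33.9%, a test whose outcome is fixed because 11 of the 12 genes have 1 site over both lists. Short genes, few sites per gene and chance may each contribute and cannot be told apart here. No biological explanation was tested.

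Ends of overlapping sites often fell on the same base, with the same start in 1169 of 2202 pairs (53.1%), the same end in 1169 and both in 703 (31.9%). The number with the same start was 27.6 times the mean number per base at distances of 1 to 10 bases (42.3). This ratio restates the pattern and does not test its source. Sites trimmed at fixed positions such as annotated exon ends are a candidate explanation that stays open, since site ends were not compared with exons here. No biological explanation was tested.

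A fold of 3.19 was held by 557 sites of list 1 (9.22%) and 2.67 by 592 sites of list 2 (7.18%), with the next most common values at 4.78 (216 sites) and 4.01 (240 sites). Of the sites without a partner, 1849 of list 1 (48.4%) and 3249 of list 2 (53.8%) lay in genes without any site in the other list. The median genomic span was 45702 bases for genes in both lists and 28102 for genes in a single list.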
